A study of Mus musculus with 12 samples.

How the data were processed

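RNA was measured in 12 samples of mouse embryoid bodies, aggregates of differentiating embryonic stem cells, of C57BL/6 origin. A floxed line, 4_1, carries Gcn5 (gene symbol Kat2a, a histone acetyltransferase of the SAGA and ATAC complexes) flanked by recombination sites, and a null line, 4C2, lacks it by the labels. Each of the 4 groups of genotype and day (day 3 and day 5 of differentiation) holds 3 samples by the labels, although the text of the series speaks of duplicates. With 1 line per genotype, the line and the genotype cannot be told apart, and p-values between genotypes measure the spread between samples of 1 line each, which may be technical. Libraries were stranded total RNA libraries made with 8 PCR cycles.

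The deposited table gives 1 signal value per gene and sample, which the authors made by dividing read counts by 1 size factor per sample. The submitters' notes name CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.0, DESeq 1.16.0 and the build mm10, without giving the role of each. Every nonzero value was a whole multiple of the smallest value in its column (100% of values, tolerance 0.01), and the whole reads recovered this way gave back the same size factors. The table lists 18269 genes, each with at least 10 reads in at least 1 library; the filter behind this is not stated. The notes do not say whether counting used the strand, so values of genes that overlap another on the opposite strand (Zic1 with Zic4, Cdk4 with Tspan31, Aldoa with Fam57b, Ackr4 with Acad11, Sycp3 with Chpt1, Irf7 with Phrf1, Cp with Hps3, Tada1 with Pogk) may hold reads of both. Gene symbols and positions came from the GENCODE M21 annotation of the same build by gene ID without its version. It held 18199 of the IDs, 12740 of them in the same version, and left 70 without a symbol.

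Recovered reads numbered 23090915 to 29446068 per floxed library and 18022071 to 26803369 per null library. The most abundant gene, Gm26917, took 1.71% to 3.00% of the reads. Within groups, log2 values correlated at r = 0.982 to 0.990 across genes, which are not independent replicates, and no 2 libraries were near copies (lowest chi-squared per degree of freedom 10.7). The first principal component (60.2% of variance) separated the days, the second (14.5%) the genotypes, and along the third (5.89%) 3 of the 4 libraries numbered 3 lay apart from the others, while that of floxed day 3 did not.

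The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1) with 4 group means over all 12 samples, 8 residual and 5.00 prior degrees of freedom. It covered the 17000 genes with a mean value of at least 10 in at least 1 group; 1269 genes fell below. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. The 5 contrasts were null against floxed at day 3 and at day 5, day 5 against day 3 in each line, and the genotype by day interaction. Log2 changes are given ± SE from limma, and values per group as mean normalised read count ± SD (n = 3).

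The 33 gene lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation called none of them in any contrast, so that p stands beside each call. Fry, a rotation test of each list alone, was a further alternative. Genes called in a list were counted with adjustment over all genes tested and adjusted over the list alone. List members not in the table or too low to test, such as Mesp1, Hand2, Tbx5, Xist, Taf9 and most Hoxc and Hoxd genes, were not analysed here.

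Kat2a and Kat2b were named first in each comparison, and Myc, Fgf5, Fgf8, Dusp6, Spry4 and T in each genotype comparison whatever their result. Also named were the 8 largest rises and 8 largest falls per genotype comparison (5 each in the others) among called genes with a mean of at least 100 in the higher group, non-overlapping samples and no clone-type name, and list members with the smallest p (at most 4 per list in genotype comparisons, 3 in the others). The interaction was not asked for non-overlapping samples. Outside this rule, Igf2 and Dlk1 in the genotype comparisons, Igf2r at day 3 and Sgce at day 5 were named for the imprinted genes after the data were seen. The rule takes 2 further genes that are not reported here.

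The same replicate number might mark samples grown together. Deviations from the group mean correlated across genes between same-numbered null and floxed samples (r = 0.270 to 0.372 at day 3, 0.247 to 0.424 at day 5). Samples of different number reached at most -0.0175 and 0.0268 there. Between days the contrast was weaker. Same-numbered samples had 0.123 to 0.282 in the null line, against at most 0.0521 for others. In the floxed line they had 0.0814 to 0.214, against at most 0.124, so these ranges overlap. The replicate number was therefore added as a block in an alternative fit. Other alternatives were upper-quartile and TMM scaling, other filters and pseudocounts, a test against a 1.5-fold change, the compared groups alone, each library left out in turn, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, libraries numbered 3 left out, chromosome 11 genes left out or centred, and a correction for GC content and length with the block.

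The test was also tested on simulated data: negative binomial counts drawn from the genes' own means and dispersions, in which 200 genes with a mean of at least 50 were changed by known folds. At day 3, limma recovered 60%, 80%, 100% and 100% of 50 genes each at 1.5-, 2-, 4- and 8-fold, with 10 false calls among 16463 genes. At day 5 it recovered 38%, 90%, 98% and 100%, with 9 false calls among 16493 genes. Both days were simulated from the same means and dispersions, so their rates differ by the random draw and not by day. Libraries were drawn independently, and at day 5 far fewer genes were changed than were called in the data. These rates may therefore not carry over to the real comparisons.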

Results

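Gene expression was profiled by stranded total RNA sequencing in embryoid bodies of a Gcn5 floxed line and a Gcn5 null line at days 3 and 5 of differentiation, with 3 samples in each of the 4 groups. Reads recovered for the listed genes numbered 23090915 to 29446068 per floxed library and 18022071 to 26803369 per null library. The series asks how loss of Gcn5 changes gene expression early in embryoid body differentiation, with FGF signalling and Myc as its named subjects. Positions are on the mm10 build.

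Null and floxed embryoid bodies at day 3 were compared to ask which genes depend on Gcn5 early in differentiation. Kat2a itself (ENSMUSG00000020918.14, chromosome 11, 100704746 to 100712465), the gene for Gcn5, had 2228 ± 151 normalised reads in floxed and 701 ± 122 in null samples, a log2 change of -1.68 ± 0.11 (adjusted p = 1.01e-05). The file has 1 value per gene, so whether the reads left in null samples lie outside the deleted part is not known. Kat2b (ENSMUSG00000000708.14, chromosome 17, 53566861 to 53672720), the gene for the related acetyltransferase PCAF, stood at 1431 ± 173 and 1595 ± 174 (0.16 ± 0.14, adjusted p = 0.533). Dusp6 (ENSMUSG00000019960.7, chromosome 10, 99263231 to 99267489), a phosphatase that acts on ERK, fell from 1843 ± 47.9 to 1148 ± 113 (-0.69 ± 0.15, adjusted p = 0.0189). Fgf5 (ENSMUSG00000029337.2, chromosome 5, 98254184 to 98277030), an FGF ligand typical of primed epiblast, fell from 219 ± 28.0 to 92.3 ± 19.8 (-1.25 ± 0.30, adjusted p = 0.0274). Values for Myc (ENSMUSG00000022346.14, chromosome 15, 61985391 to 61990374) were 172 ± 31.6 and 113 ± 28.7 (-0.62 ± 0.30, adjusted p = 0.240), which passed the test with the replicate block (adjusted p = 0.0225). Differences did not pass the test for Spry4 (ENSMUSG00000024427.6, chromosome 18, 38586247 to 38601415), an inhibitor of receptor tyrosine kinase signalling (-0.61 ± 0.34), Fgf8 (ENSMUSG00000025219.13, chromosome 19, 45736798 to 45742915, -0.42 ± 0.38), or T (ENSMUSG00000062327.10, chromosome 17, 8434423 to 8442496), a transcription factor of the primitive streak (-0.59 ± 0.59). The Fgf8 value turned positive (0.15) without floxed day 3 replicate 3, whose count of 674 stood against 203 and 209 in the other floxed libraries. The Dusp6 and Fgf5 calls were lost when single day 3 libraries were left out. Without null replicate 3, their adjusted p was 0.0679 and 0.0934. For Dusp6 it was 0.0640 without null replicate 1, 0.0581, 0.0525 and 0.0509 without floxed replicates 1, 2 and 3, and for Fgf5 0.0835 without null replicate 1 and 0.0910 and 0.0871 without floxed replicates 1 and 2.

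**Figure D1:**
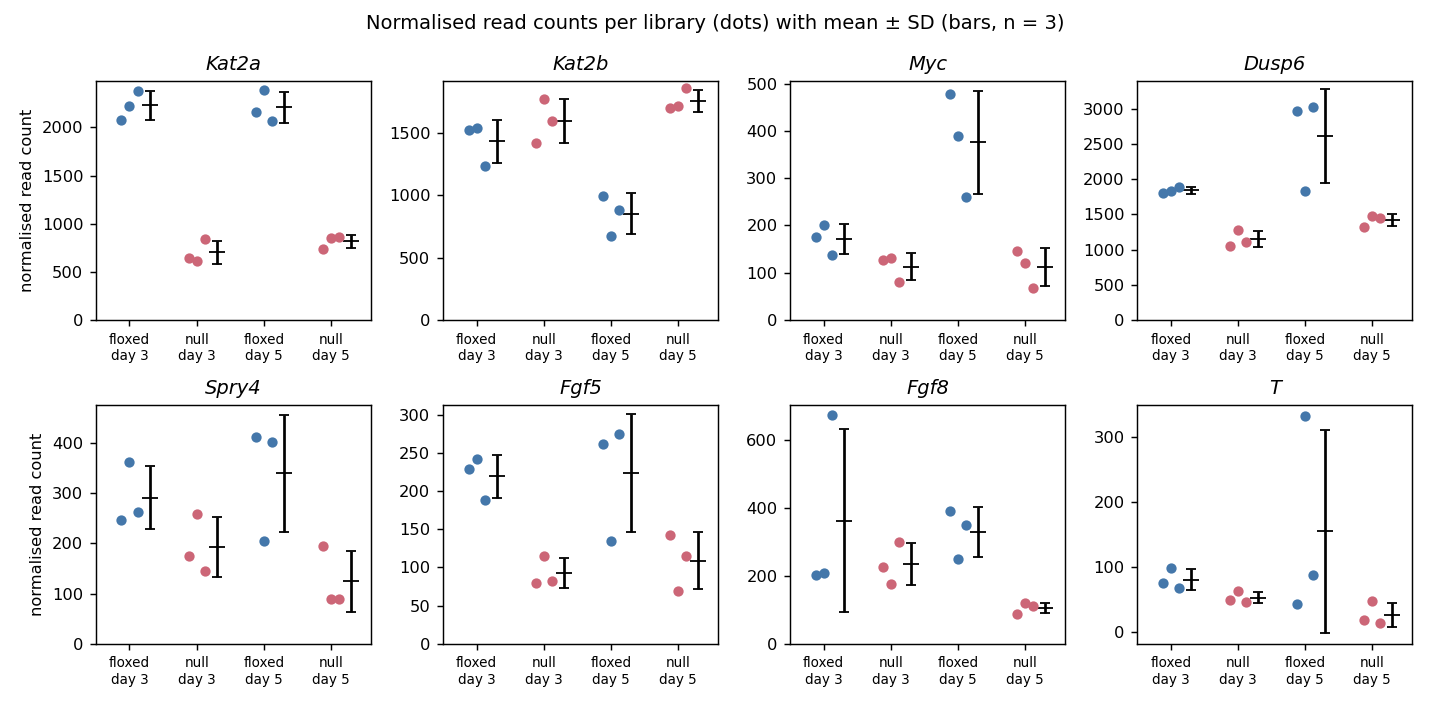
Normalised read counts of 8 named genes in each of the 12 libraries, by genotype and day; dots are libraries, and bars show the mean and SD of 3. Kat2a means were 2228 and 2207 in floxed and 701 and 817 in null samples, while Kat2b at day 5 averaged 851 in floxed and 1754 in null samples.

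The falls of greatest size at day 3 were among imprinted genes, which are expressed from 1 parental copy. The long noncoding RNAs Rian (2408 ± 859 to 107 ± 83.3, -4.67 ± 0.49) and Meg3 (411 ± 113 to 18.9 ± 8.74, -4.43 ± 0.71) from chromosome 12 fell, as did H19 (-3.02 ± 0.47) and the cell cycle inhibitor Cdkn1c (-1.90 ± 0.26) from chromosome 7 and the signalling adaptor Grb10 (11087 ± 1989 to 1345 ± 289.7, -3.05 ± 0.17) from chromosome 11. Mirg, next to Rian, fell by 4.96 on the log2 scale, and Sgce, expressed from the paternal copy, rose by 1.20. Igf2r, which lies on chromosome 17, fell (-0.33 ± 0.09, adjusted p = 0.0455). Of 24 imprinted genes tested, 4 rose and 7 fell (7 and 9 adjusted over the list alone). The list did not pass its test (adjusted p = 0.605), and its median change was 0.08 while its mean (-0.66) and test pointed down. Outside the list, the homeobox gene Meis2 (-1.95 ± 0.47) and the synaptic gene Cplx2 (-1.59 ± 0.43) fell, calls that were lost without single libraries. Meis2 had an adjusted p of 0.0909 and 0.0648 without null replicates 2 and 1, and 0.0776 and 0.0666 without floxed replicates 1 and 3. For Cplx2 it was 0.142, 0.116 and 0.0600 without null replicates 1, 2 and 3, and 0.0976 and 0.0951 without floxed replicates 1 and 3, the last with a log2 change of -0.97. For Igf2r it was 0.0585, 0.133 and 0.0626 without null replicates 1, 2 and 3, and 0.0610, 0.112 and 0.131 without floxed replicates 1, 2 and 3. Igf2r was also lost with upper-quartile scaling (adjusted p = 0.0525) and edgeR (0.0514), and Cplx2 with upper-quartile scaling (0.0504).

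The 8 greatest rises at day 3 included 4 genes of the X chromosome, Usp26 (2.15 ± 0.28), Nxf3 (2.11 ± 0.14), Pnma5 (2.05 ± 0.29) and Asb9 (2.01 ± 0.33). Ddx60 (2.06 ± 0.35) and Gbp3 (1.98 ± 0.35), both inducible by interferon, Ndrg1 (1.85 ± 0.24), inducible by hypoxia, and Ace (1.84 ± 0.28), the angiotensin-converting enzyme on chromosome 11, made up the rest. Of 25 glycolysis and hypoxia genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.36), including Adm (1.54 ± 0.27), the vasodilator adrenomedullin, P4ha2 (0.94 ± 0.12), a collagen prolyl hydroxylase, and Pdk1 (0.70 ± 0.11), a kinase that inhibits pyruvate dehydrogenase. That list passed the camera test at adjusted p = 4.59e-09 (adjusted p = 0.912 with an estimated correlation). Fry called 0 lists at day 3, so this call and the other list calls of this day were lost with it. Among 16 interferon response genes, 3 rose (7 adjusted over the list alone, median 0.80), namely Oasl2 (1.41 ± 0.22), the RNA sensor Ifih1 (1.49 ± 0.36) and the transcription factor Irf1 (0.80 ± 0.20). The list passed at adjusted p = 0.000201 (adjusted p = 0.912 with an estimated correlation). Without null replicate 3 the interferon median was 0.53. Of 14 feeder fibroblast markers, 4 rose and 0 fell at this day (4 and 1 adjusted over the list alone), and their list did not pass (adjusted p = 0.605; median -0.06, mean 0.03 and an upward test). The Ifih1 call was lost without null replicate 3 (adjusted p = 0.121), null replicate 2 (0.0661) or floxed replicate 1 (0.0819). That of Irf1 was lost without null replicates 2 (0.0714) and 3 (0.130) or floxed replicates 1 (0.132), 2 (0.0634) and 3 (0.0513). Of 26 ERK target and feedback genes, 3 fell and 1 rose (6 and 2 adjusted over the list alone, median -0.29). Spry2 (-0.80 ± 0.13) and Spred3 (-0.98 ± 0.26) fell and Ier3 rose (1.53 ± 0.32). That list passed at adjusted p = 0.0245 (adjusted p = 0.977 with an estimated correlation), and without null replicate 3 its adjusted p was 0.0858. Its median was -0.45 without null replicate 1. The Ier3 call was lost without null replicate 1 (adjusted p = 0.0514). That of Spred3 was lost without null replicates 1 (0.138) and 3 (0.135) or floxed replicates 1 (0.0782), 2 (0.0986) and 3 (0.121), and with edgeR (0.0531). Myc targets and ribosome biogenesis passed downward at adjusted p = 0.0479 (adjusted p = 0.977 with an estimated correlation) with a median of -0.10, although 6 of 66 members rose and 3 fell (6 and 5 adjusted over the list alone). The risers Tmem97 (0.55 ± 0.08), C1qbp (0.43 ± 0.07) and Pes1 (0.37 ± 0.07) lie on chromosome 11, and Cdk4 (-0.43 ± 0.08) fell. The Myc target call was lost without null replicate 3 (adjusted p = 0.138, median -0.07), null replicate 1 (0.356, median -0.07) or floxed replicate 2 (0.352). The Pes1 call was lost without null replicate 3 (0.0550) or floxed replicate 1 (0.0532).

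In all, 1041 of 17000 genes changed at day 3 (696 higher and 345 lower in null samples, limma). Chromosome 11 held 404 of the 696 higher genes (58.0%) and 3 of the 345 lower ones, against 7.84% of the genes tested. The median log2 change of its expressed genes was 0.35 at day 3 and 0.30 at day 5, with 91.9% and 84.3% of them above 0, while medians of the other autosomes lay between -0.07 and -0.01 at day 3 and between -0.10 and -0.02 at day 5. Kat2a and Grb10 lie on this chromosome. The SAGA deubiquitinase gene Usp22 and the adaptor gene Tada2a also lie there and rose (0.44 ± 0.07 and 0.33 ± 0.07). Taf9b on the X chromosome rose (0.72 ± 0.17), a call lost without null replicates 2 (adjusted p = 0.0579) and 3 (0.119) or floxed replicates 1 (0.0904) and 2 (0.0964). Over the 30 SAGA and ATAC subunits 3 rose and 1 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.713). Against a 1.5-fold change the balance turned, to 1 higher and 7 lower. With chromosome 11 genes left out, 388 genes changed, 179 higher and 209 lower. With that chromosome centred, 456 changed, 210 higher and 246 lower (46.1% higher, against 66.9%). Centring ended the calls of Tmem97 (0.17), C1qbp (0.05), Usp22 (0.06) and Irf1 (0.42), and turned Pes1 (-0.01) and Tada2a (-0.05) negative. It also ended those of Cplx2 (adjusted p = 0.0723), Spred3 (0.0659) and Igf2r (0.0682), whose values it did not move. Leaving the chromosome out ended the same 3 calls (0.0746, 0.0681 and 0.0705) and that of Ifih1 (0.0505). The replicate block gave 1866 genes (58.7% higher), and 48.3% higher with a correction for GC content and length as well. The count fell to 426 without null day 3 replicate 3, to 442 without floxed day 3 replicate 1 and to 650 without floxed day 3 replicate 2.

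**Figure D2:**
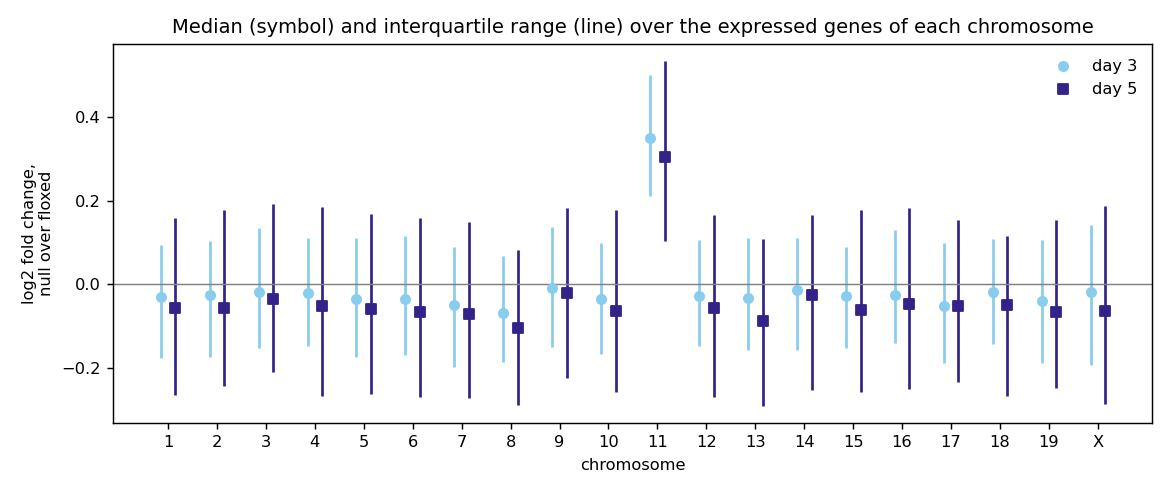
Log2 fold change of null over floxed samples by chromosome at day 3 (circles) and day 5 (squares); symbols are medians over the expressed genes of a chromosome and lines span the middle quartiles. Chromosome 11 stands at 0.35 and 0.30, apart from the other autosomes.

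At day 5, null and floxed embryoid bodies were compared to ask the same question later in differentiation. Kat2a was again lower in null samples, at 2207 ± 165 in floxed and 817 ± 67.5 in null samples (-1.43 ± 0.11, adjusted p = 1.6e-05). Kat2b was higher, at 851 ± 163 and 1754 ± 88.4 (1.06 ± 0.14, adjusted p = 0.000276). Myc was lower, at 376 ± 109 and 112 ± 39.8 (-1.76 ± 0.30, adjusted p = 0.00140). Of the FGF and ERK genes, Dusp6 (-0.85 ± 0.15), Spry4 (-1.48 ± 0.34), Fgf8 (329 ± 72.1 to 106 ± 15.7, -1.62 ± 0.38) and Fgf5 (-1.03 ± 0.30) fell, and so did T (155 ± 156 to 26.8 ± 18.4, -2.18 ± 0.59). The adjusted p of Fgf5 was 0.0953 without null day 5 replicate 2 and 0.0855 and 0.0853 without floxed day 5 replicates 3 and 1. That of T was 0.0681 and 0.0539 without null day 5 replicates 3 and 1, and its log2 change was -1.37 without floxed day 5 replicate 2. Of the 37 called genes named at day 3, 11 were lost without some single library and 26 were kept. At day 5, 6 of 75 were lost and 69 kept. Null and floxed libraries overlapped for Fgf5, T and Tdgf1 at day 5.

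The ERK target and Wnt target lists were lower in null samples at day 5. Of 26 ERK target and feedback genes, 14 fell and 3 rose (14 and 3 adjusted over the list alone, median -0.89, adjusted p = 0.000565, and adjusted p = 0.358 with an estimated correlation). Spry2 (-1.29 ± 0.13), Spry1 (-1.09 ± 0.13) and Ccnd1 (-0.94 ± 0.13), the gene for cyclin D1, fell, and Egr1 (1.54 ± 0.24), an immediate early gene, rose. Among 14 Wnt pathway targets, 7 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.65, adjusted p = 0.0471, and adjusted p = 0.389 with an estimated correlation). Lgr5 (-1.72 ± 0.30), Apcdd1 (-1.10 ± 0.21) and Fgf17 (-1.38 ± 0.29) fell and Tcf7 (0.71 ± 0.07), on chromosome 11, rose. The Wnt call was lost without floxed day 5 replicate 1 (adjusted p = 0.0563), floxed day 5 replicate 2 (0.0664) or null day 5 replicate 3 (0.116). Of 28 FGF ligands, receptors and co-receptors, 8 fell and 2 rose (8 and 2 adjusted over the list alone), with Fgf15 (-2.70 ± 0.38) and Fgf3 (-1.50 ± 0.31) lower and Fgf11 (1.54 ± 0.22), on chromosome 11, higher. The list did not pass (adjusted p = 0.0523).

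Lists of Myc targets, cell cycle, cholesterol synthesis and stress response genes were lower as well. Of 66 Myc targets and ribosome biogenesis genes, 43 fell and 1 rose (49 and 2 adjusted over the list alone, median -0.36, adjusted p = 3.76e-13, and adjusted p = 0.358 with an estimated correlation). Examples are the polyamine enzymes Srm (-0.94 ± 0.10) and Odc1 (-0.78 ± 0.07), and Cdk4 (-0.61 ± 0.08). Of 31 cell cycle and proliferation genes, 15 fell and 2 rose (17 and 6 adjusted over the list alone, median -0.23, adjusted p = 0.00200, and adjusted p = 0.505 with an estimated correlation), among them the replication genes Pcna (-0.56 ± 0.07), Rrm2 (-0.54 ± 0.07) and Mcm5 (-0.47 ± 0.06). Cholesterol synthesis (5 of 19 fell, 7 adjusted over the list alone, adjusted p = 0.00299, and adjusted p = 0.577 with an estimated correlation) and the integrated stress and unfolded protein response (9 of 20 fell and 1 rose, 10 and 1 adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.577 with an estimated correlation) were lower too. Their members included Idi1 (-0.60 ± 0.15), Hspa5 (-0.42 ± 0.08), Herpud1 (-0.83 ± 0.16) and the serine synthesis gene Psat1 (-0.63 ± 0.12), while Xbp1 (0.39 ± 0.07), on chromosome 11, rose, a call lost with that chromosome centred (0.03, adjusted p = 0.819). Without floxed day 5 replicate 1 the stress list had an adjusted p of 0.0661. Of 12 genes of the Myc family, 3 fell and 2 rose (4 and 2 adjusted over the list alone, list adjusted p = 0.515).

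The naive pluripotency, primed epiblast, primitive streak and neural ectoderm lists were lower in null samples at day 5. Of 20 naive pluripotency genes, 10 fell and 0 rose (12 and 1 adjusted over the list alone, median -0.80, adjusted p = 0.000176, and adjusted p = 0.505 with an estimated correlation), among them Nr0b1 (-2.40 ± 0.40), Tdh (-2.11 ± 0.39), Esrrb (-1.48 ± 0.32) and Sox2 (3369 ± 221 to 1992 ± 68.4). Of 18 primed epiblast genes, 8 fell (12 adjusted over the list alone, median -0.55, adjusted p = 0.00148, and adjusted p = 0.358 with an estimated correlation), with Lin28b (-0.52 ± 0.12), Otx2 (-1.08 ± 0.29) and Tdgf1 (-1.79 ± 0.51) lower. The Otx2 call was lost without floxed day 5 replicate 1 (adjusted p = 0.0577) or null day 5 replicate 2 (0.0546). That of Tdgf1 was lost without floxed day 5 replicates 1 (0.0656) and 3 (0.0829) or null day 5 replicate 2 (0.0867). In the primitive streak and early mesoderm list 7 of 22 fell (9 adjusted over the list alone, median -0.84, adjusted p = 0.0175, and adjusted p = 0.505 with an estimated correlation), among them Rspo3 (-2.38 ± 0.44), Wnt3a (-1.60 ± 0.39) and Nodal (-1.36 ± 0.36). With chromosome 11 genes left out the list did not pass (adjusted p = 0.0761, median -0.59). Without floxed day 5 replicate 3 the list's adjusted p was 0.0997 and that of Nodal 0.0643, and without floxed day 5 replicate 1 that of Nodal was 0.0530. Without null day 5 replicate 2 the log2 change of Nodal was -0.87. Of 26 neural ectoderm genes, 4 fell (4 adjusted over the list alone, median -0.78, adjusted p = 0.00276, and adjusted p = 0.505 with an estimated correlation), including the transcription factors Zic1 (991 ± 344 to 97.3 ± 21.7, -3.30 ± 0.50) and En2 (-2.76 ± 0.55) and the fatty acid binding protein gene Fabp7 (-1.89 ± 0.48). The Fabp7 call was lost without null day 5 replicate 1 (adjusted p = 0.0507), and its log2 change was -1.24 without floxed day 5 replicate 3. The noncoding RNA Pantr1 (-3.48 ± 0.80) and the eye-field gene Six6 (-3.28 ± 0.81) were among the 8 greatest falls.

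Imprinted genes made up the other large falls at day 5. Grb10 fell from 22128 ± 3698 to 216 ± 26.5 (-6.66 ± 0.17), Cdkn1c from 2457 ± 203 to 284 ± 137 (-3.22 ± 0.26) and H19 from 4234 ± 1600 to 568 ± 332 (-3.06 ± 0.47), along with Meg3 (-3.93 ± 0.71), Rian (-3.77 ± 0.49), Mirg (-3.91 ± 0.43) and Igf2r (-1.12 ± 0.09), a receptor that clears IGF2. Of the 24 imprinted genes, 9 fell and 6 rose (9 and 6 adjusted over the list alone, median -0.37, adjusted p = 0.0330, and adjusted p = 0.406 with an estimated correlation). Without floxed day 5 replicate 2 the adjusted p was 0.0531, and with chromosome 11 genes centred 0.0575 or left out 0.169. Sgce rose from 584 ± 68.8 to 1172 ± 133. The 8 genes known to be expressed from the maternal copy had a median change of -3.04 at day 3 and -3.49 at day 5, against 0.44 and 0.15 for the 16 expressed from the paternal copy (two-sided exact permutation p = 0.000163 at both days, n = 8 and 16). Genes of the same imprinted region are not independent, and the grouping by parental copy was chosen after the values were seen. At day 3, 7 of the 8 maternal genes fell, and of the paternal genes 4 rose and 0 fell. At day 5, 8 of the 8 maternal genes fell, and of the paternal genes 6 rose and 1 fell.

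**Figure D3:**
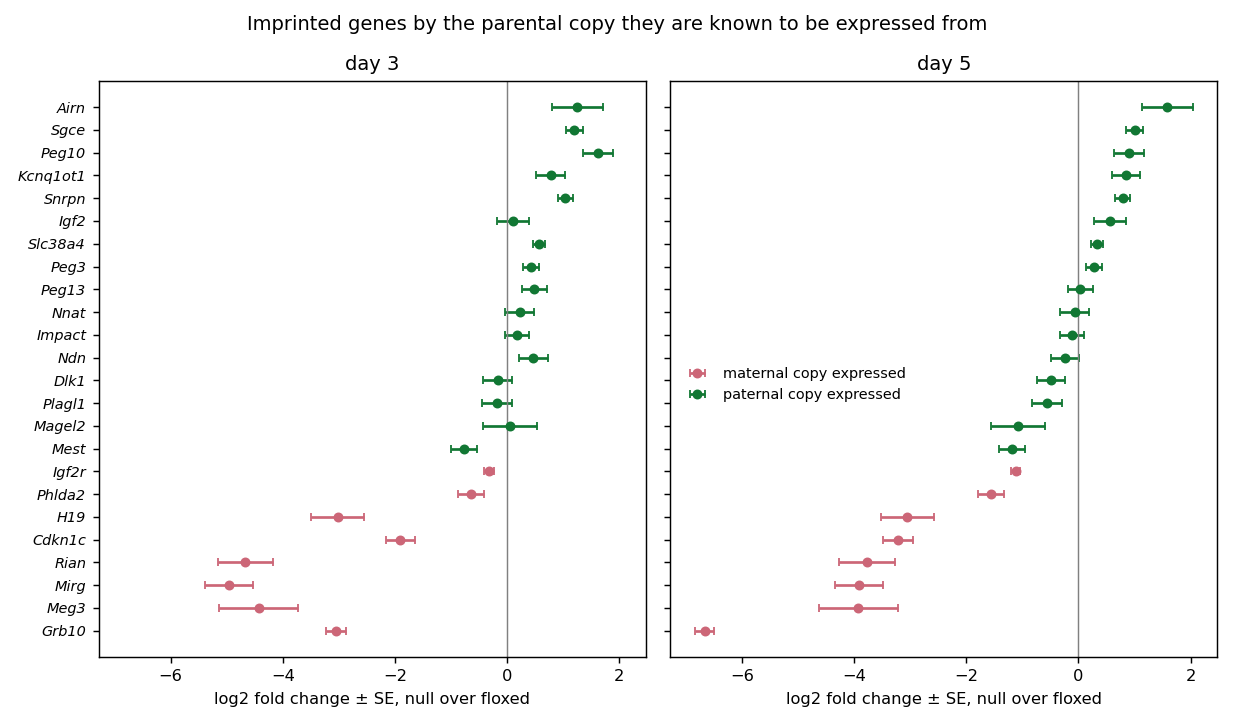
Log2 fold change ± SE (null over floxed samples, n = 3 each) of 24 imprinted genes at days 3 and 5, by the parental copy known to be expressed. The 8 maternal genes lie below 0 at both days, with medians of -3.04 and -3.49.

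Interferon response genes were higher in null samples at day 5. Of 16 tested, 12 rose (14 adjusted over the list alone, median 1.70, adjusted p = 2.69e-08, and adjusted p = 0.358 with an estimated correlation). Rsad2 (130.2 ± 42.4 to 825 ± 168, 2.70 ± 0.46), Ifit1 (3.36 ± 0.41), Irf7 (2.37 ± 0.37), Oasl2 (2.05 ± 0.22) and Irf1 (1.31 ± 0.20) rose, as did Ddx60 (2.90 ± 0.35), Gbp11 (3.09 ± 0.57) and Irgm2 (2.52 ± 0.30). These 3 and Rsad2 were among the 8 greatest rises named, which asks for a mean of at least 100. The others were Adm (33.9 ± 6.90 to 374 ± 29.0, 3.44 ± 0.27), Hsd11b1 (3.10 ± 0.49), Erg (2.97 ± 0.63), a transcription factor of endothelium, and Mat1a (2.83 ± 0.74). Of 25 glycolysis and hypoxia genes, 15 rose (16 adjusted over the list alone, median 0.51, adjusted p = 2.69e-08, and adjusted p = 0.389 with an estimated correlation), including Aldoa (23203 ± 3097 to 40897 ± 2971), Pdk1 (0.88 ± 0.11) and P4ha2 (0.87 ± 0.12). Germ cell and 2-cell-like genes (6 of 18 rose and 1 fell, 6 and 1 adjusted over the list alone, adjusted p = 0.0196, and adjusted p = 0.577 with an estimated correlation) included Ddx4 (1.29 ± 0.14), Sycp1 (1.60 ± 0.25) and Stk31 (2.14 ± 0.35). Without floxed day 5 replicate 2 or null day 5 replicate 3 that list had an adjusted p of 0.255 or 0.0721 and a median of 0.01 or 0.14, against 0.43 with all. The median was 0.67 and 0.90 without floxed day 5 replicate 1 and null day 5 replicate 2. Epithelial adhesion genes (4 of 14 rose, 4 adjusted over the list alone, adjusted p = 0.0290, and adjusted p = 0.577 with an estimated correlation) included Ocln (1.64 ± 0.14), a tight junction protein, and Epcam (0.85 ± 0.08). Their adjusted p was 0.213 without floxed day 5 replicate 3, and 0.104 and 0.102 without null day 5 replicates 1 and 2, with medians of 0.02, 0.04 and 0.11 against 0.20 with all. Without null day 5 replicate 3 the median was 0.37. Of 30 SAGA and ATAC subunits, 7 fell and 2 rose (7 and 2 adjusted over the list alone, list adjusted p = 0.0942), with Tada1 at -0.68 ± 0.15 and Taf5l at -0.55 ± 0.08.

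**Figure D4:**
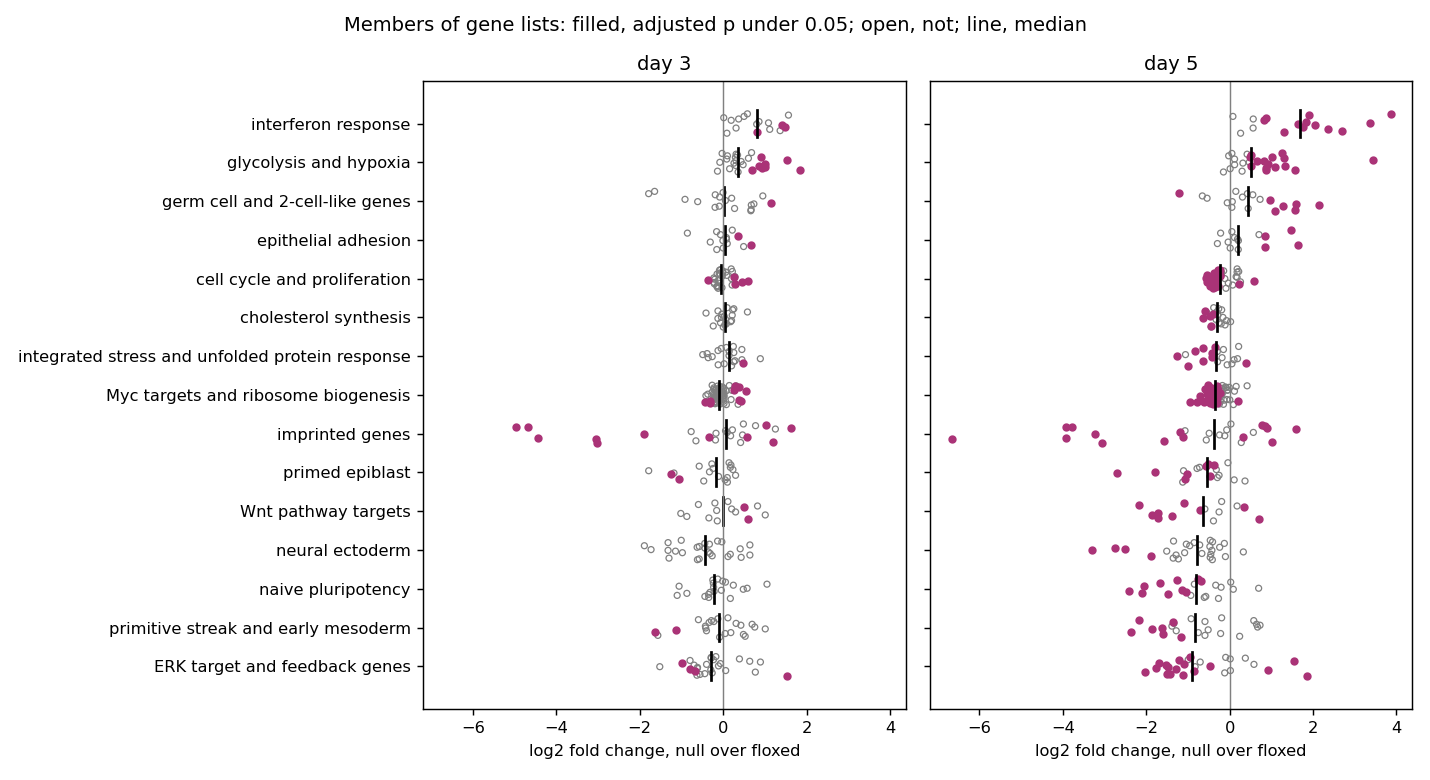
Log2 fold change (null over floxed samples) of the members of the 15 gene lists that passed the camera test at day 5, at day 3 and day 5; filled points are genes with an adjusted p under 0.05 and lines are medians. At day 5 the medians run from -0.89 for ERK target and feedback genes to 1.70 for interferon response genes.

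In all, 4509 genes changed at day 5, 2217 higher and 2292 lower in null samples (limma). With upper-quartile scaling the balance turned, to 2472 higher and 1879 lower, and with TMM to 2326 and 2089. It was 1633 higher and 2196 lower without chromosome 11 genes, 1771 and 2399 with that chromosome centred, and 151 and 52 against a 1.5-fold change. Chromosome 11 held 550 of the higher genes (24.8%) and 35 of the lower ones. Of the genes higher at day 3, 498 were also higher at day 5 and 302 of these lie on chromosome 11. Elsewhere 196 of 292 were shared, where 31.1 would be by independent draws. Of the genes lower at day 3, 234 of 345 were lower at day 5. No difference between the counts of the days was tested by these numbers; the interaction tests it gene by gene.

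In the floxed line, day 5 was compared with day 3 for the course of differentiation with Gcn5 present. Kat2a did not pass the test (-0.01 ± 0.11, adjusted p = 0.937), and Kat2b fell (-0.76 ± 0.14, adjusted p = 0.000662). Genes of neural ectoderm rose (22 of 26, 1 fell, 23 and 1 adjusted over the list alone, median 3.49, adjusted p = 1.97e-09, and adjusted p = 0.216 with an estimated correlation), among them Zic1 (19.6 ± 19.9 to 991 ± 344), Pax3 (24.9 ± 18.5 to 963 ± 330.4) and Wnt1 (0.302 ± 0.524 to 104 ± 56.9). The 5 greatest rises were Cyp26b1 (4.95 ± 2.06 to 1217 ± 348), an enzyme that breaks down retinoic acid, Cp (0.323 to 220.4 ± 67.5), Dbx1 (0.927 to 318 ± 242), Frzb (11.8 ± 14.4 to 1109 ± 364) and Wnt3a (3.02 ± 2.21 to 366 ± 104), several from near 0 at day 3, so folds of these depend on the added 1. The greatest falls were Ackr4 (-4.18 ± 0.33), Fam43b (-4.08 ± 0.44), Ephx3 (-3.92 ± 0.40), Tll1 (-3.91 ± 0.31) and the Nodal inhibitor Lefty1 (-3.67 ± 0.58).

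Further lists changed in the floxed line. In extraembryonic endoderm, 19 of 25 genes rose and 1 fell (20 and 2 adjusted over the list alone, adjusted p = 2.44e-05, and adjusted p = 0.355 with an estimated correlation), including Lama1 (3.10 ± 0.30), Sparc (1.46 ± 0.12) and Foxa2 (2.59 ± 0.29). Mesenchymal genes such as Cdh11 (5.73 ± 0.28) and Cdh2 (3.02 ± 0.25) rose (6 of 12, 7 adjusted over the list alone, adjusted p = 0.000448, and adjusted p = 0.216 with an estimated correlation), and so did feeder fibroblast markers (9 of 14, 1 fell, 10 and 1 adjusted over the list alone, median 1.27, adjusted p = 0.00185, and adjusted p = 0.216 with an estimated correlation). Imprinted genes rose as a list (14 of 24, 3 fell, 15 and 3 adjusted over the list alone, adjusted p = 0.00039, and adjusted p = 0.216 with an estimated correlation), among them Igf2 (3.46 ± 0.29) and Dlk1 (3.21 ± 0.25). Glycolysis and hypoxia genes fell (22 of 25, 22 adjusted over the list alone, adjusted p = 1.33e-11, and adjusted p = 0.216 with an estimated correlation), with Adm (-3.65 ± 0.27), Aldoa (-1.50 ± 0.10) and Eno1 (-1.01 ± 0.08). Cholesterol synthesis fell (18 of 19, 19 adjusted over the list alone, adjusted p = 4.54e-10, and adjusted p = 0.289 with an estimated correlation), with Dhcr7 at -1.14 ± 0.10. Germ cell and 2-cell-like genes fell (13 of 18, 14 adjusted over the list alone, adjusted p = 7.57e-05, and adjusted p = 0.327 with an estimated correlation), with Sycp3 (-2.14 ± 0.25) and Ddx4 (-1.28 ± 0.14). Naive pluripotency genes went both ways (9 of 20 rose and 4 fell, 10 and 4 adjusted over the list alone, list adjusted p = 0.176), with rises of Klf4 (1.54 ± 0.21), Nr5a2 (1.79 ± 0.22) and Sox2 (0.56 ± 0.07). In all, 7094 genes changed, 3824 higher and 3270 lower at day 5 (limma).

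In the null line, day 5 was compared with day 3 for the course of differentiation without Gcn5. Neither Kat2a (0.23 ± 0.11, adjusted p = 0.118) nor Kat2b (0.14 ± 0.14, adjusted p = 0.421) passed the test. Neural ectoderm genes rose (20 of 26, 1 fell, 22 and 1 adjusted over the list alone, median 3.03, adjusted p = 1.89e-07, and adjusted p = 0.228 with an estimated correlation), among them Pax3 (9.93 ± 8.50 to 364 ± 69.5) and Wnt1 (0 to 62.0 ± 24.1). Frzb (4.46 ± 0.436 to 974 ± 380.4), Dbx1 (0.894 to 244 ± 205), Cyp26c1 (2.68 ± 2.68 to 239 ± 121) and Ednrb (10.4 ± 13.5 to 487 ± 251) were among the 5 greatest rises. Ephx3 (-5.13 ± 0.40), Lefty1 (-4.86 ± 0.58), Ackr4 (-4.45 ± 0.33), Kirrel2 (-4.22 ± 0.39) and Galr2 (-3.90 ± 0.32) fell most. Myc targets and ribosome biogenesis genes fell (50 of 66, 1 rose, 52 and 1 adjusted over the list alone, adjusted p = 9.16e-13, and adjusted p = 0.228 with an estimated correlation), with Odc1 (-0.97 ± 0.07) and Dkc1 (-0.86 ± 0.07). Cholesterol synthesis fell (19 of 19, 19 adjusted over the list alone, adjusted p = 1.09e-12, and adjusted p = 0.228 with an estimated correlation), with Insig1 (-2.32 ± 0.18) and Dhcr7 (-1.56 ± 0.10), as did the integrated stress and unfolded protein response (16 of 20, 17 adjusted over the list alone, where 1 rose, adjusted p = 3.17e-06, and adjusted p = 0.228 with an estimated correlation), with Psat1 (-1.23 ± 0.12) and Asns (-0.85 ± 0.10). Interferon response genes rose (12 of 16, 12 adjusted over the list alone, where 1 fell, adjusted p = 0.00047, and adjusted p = 0.228 with an estimated correlation), with Rsad2 (3.75 ± 0.46) and Ifit1 (2.96 ± 0.41). The pluripotency genes Pou5f1 (-2.39 ± 0.26) and Dppa5a (-2.54 ± 0.29) fell, in a naive pluripotency list that did not pass (adjusted p = 0.465). In all, 7571 genes changed, 3841 higher and 3730 lower at day 5 (limma). Of the genes that rose in the floxed line, 2764 also rose in the null line, and of those that fell 2351 also fell, where independent draws would give 864 and 717.

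The genotype by day interaction asks whether the effect of genotype differed between the days. Kat2a (0.24 ± 0.16, adjusted p = 0.540) did not pass, and Kat2b (0.90 ± 0.19) did not (0.0595), though Kat2b passed with the replicate block (adjusted p = 0.0357), upper-quartile scaling (0.0491) and DESeq2 (0.00205). Grb10 had the change of greatest size (-3.61 ± 0.25, adjusted p = 2.92e-05). The genes Etv4, a transcription factor induced by FGF (-2.81 ± 0.52), Ccnd2, the gene for cyclin D2 (-2.45 ± 0.43), Cyp26b1 (-2.30 ± 0.43) and Emilin2 (-2.08 ± 0.32) had a genotype effect that was lower at day 5 than at day 3, and Afap1l2 (2.04 ± 0.37), Tgfbi (2.02 ± 0.32), Fstl4 (1.90 ± 0.33), Catsperg1 (1.89 ± 0.31) and Pdk4 (1.87 ± 0.34) one that was higher. Myc (-1.14, adjusted p = 0.243), Dusp6 (-0.16, adjusted p = 0.795) and Fgf8 (-1.20, adjusted p = 0.330) did not pass, so their effects were not shown to differ between the days. In all, 81 genes passed (42 higher and 39 lower, limma), and 443 with the replicate block. The count was 3 without floxed day 3 replicate 1, null day 3 replicate 1 or null day 5 replicate 2, 4 without null day 3 replicate 2, 5 without floxed day 3 replicate 2, 9 without null day 5 replicate 1, 16 without floxed day 5 replicate 3, 19 without null day 5 replicate 3 and 45 without floxed day 5 replicate 1. Of the 18 called genes named for the interaction, 17 were lost when some single library was left out, and Grb10 was kept in every case.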

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

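Among the tests in this part, the feeder fibroblast test, both tests of a delay and both tests of the direct dosage of chromosome 11 genes were chosen only after the result was seen.

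The effect of genotype differed between the days for 18 named genes, by the interaction term of limma (null minus floxed at day 5, less the same at day 3, log2). Among imprinted genes, Grb10 (-3.61) and Igf2r (-0.79) had a difference below 0. The same held for the ERK targets Etv4 (-2.81) and Spry1 (-1.03), and for Ccnd2 (-2.45), Cyp26b1 (-2.30), Emilin2 (-2.08), Psat1 (-0.92), Sox2 (-0.63) and Odc1 (-0.60). It was above 0 for Afap1l2 (2.04), Tgfbi (2.02), Fstl4 (1.90), Catsperg1 (1.89), Pdk4 (1.87) and Ddx4 (1.38), and for the p53 targets Btg2 (1.01) and Trp53inp1 (0.80). The adjusted p was 2.92e-05 for Grb10 and 0.0308 to 0.0383 for the others. Left out alone, floxed day 3 replicate 1, null day 3 replicate 1 or null day 5 replicate 2 ended 17 of these calls. Floxed day 3 replicate 2, null day 3 replicate 2 or null day 5 replicate 1 ended 16, null day 5 replicate 3 ended 14, floxed day 5 replicate 3 ended 13, floxed day 5 replicate 1 ended 9, null day 3 replicate 3 ended 5 and floxed day 5 replicate 2 ended 2. The adjusted p of a lost call lay between 0.0508 and 0.0989. Leaving out all libraries numbered 3 ended 11, those of Afap1l2 (0.0853), Fstl4 (0.0977), Catsperg1 (0.0925), Pdk4 (0.104), Etv4 (0.101), Cyp26b1 (0.151), Sox2 (0.107), Spry1 (0.0853), Odc1 (0.0885), Trp53inp1 (0.0899) and Ddx4 (0.0885).

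The camera test of the same difference passed for 15 lists. Their medians below 0 were those of naive pluripotency (-0.65), primed epiblast (-0.37), primitive streak and early mesoderm (-0.77), ERK target and feedback genes (-0.46), Wnt pathway targets (-0.60), Myc targets and ribosome biogenesis (-0.24), cell cycle and proliferation (-0.17), cholesterol synthesis (-0.39), the integrated stress and unfolded protein response (-0.49), imprinted genes (-0.29) and ciliary genes (-0.27). Those above 0 were interferon response (0.63), germ cell and 2-cell-like genes (0.71), epithelial adhesion (0.32) and p53 target genes (0.17). Adjusted p ran from 4.13e-15 for Myc targets to 0.0374 for ciliary genes, and with an estimated correlation none passed (adjusted p = 0.270 to 0.549 with an estimated correlation). Few members passed alone: of 66 Myc targets 1 did (12 adjusted over the list alone). The primitive streak list was lost without floxed day 3 replicate 1 (adjusted p = 0.145), floxed day 5 replicate 3 (0.158) or null day 3 replicate 3 (0.0556), the ERK list without floxed day 5 replicate 1 (0.0526) and the germ cell list without floxed day 5 replicate 2 (0.160). Epithelial adhesion was lost without floxed day 3 replicate 2 (0.161), floxed day 5 replicate 3 (0.175), null day 3 replicate 3 (0.0915) or null day 5 replicates 1 (0.0662) and 2 (0.0759). Ciliary genes were lost without floxed day 3 replicate 2 (0.161), floxed day 5 replicates 2 (0.131) and 3 (0.0973), null day 3 replicates 1 (0.0622) and 3 (0.112) or null day 5 replicate 2 (0.0620). Single libraries also moved medians by more than 1.5 times. Primitive streak stood at -0.49 and -0.47 without floxed day 3 replicate 1 and floxed day 5 replicate 3, and at -0.51 and -0.45 without null day 3 replicate 2 and null day 5 replicate 2. Epithelial adhesion stood at 0.16 and 0.13 without floxed day 3 replicate 2 and floxed day 5 replicate 3, at 0.13 without null day 3 replicate 3 or null day 5 replicate 1, and at 0.16 without null day 5 replicate 2. It rose to 0.56, 0.48 and 0.52 without floxed day 3 replicate 3, floxed day 5 replicate 2 and null day 5 replicate 3. Ciliary genes stood at -0.15, -0.18 and -0.17 without floxed day 5 replicate 2, null day 3 replicate 3 and null day 5 replicate 2. The stress list stood at -0.24 and -0.30 without floxed day 3 replicate 3 and floxed day 5 replicate 1, and primed epiblast at -0.24 and -0.22 without floxed day 5 replicate 1 and null day 5 replicate 3. The p53 targets stood at 0.09 and 0.11 without floxed day 5 replicate 3 and null day 5 replicate 2, germ cell genes at 0.42 without null day 3 replicate 2, and cell cycle genes at -0.11 without null day 3 replicate 3.

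As a group, imprinted genes expressed from the maternal copy were lower in the null line at both days. At day 3, 7 of the 8 were called lower, and Phlda2 did not pass (-0.65, adjusted p = 0.119, limma). The direct dosage of chromosome 11 genes is argued against by direction. Genes of that chromosome were higher in null samples (median 0.35 at day 3 and 0.30 at day 5). Grb10, which lies on it, fell instead (-3.05 and -6.66). The 7 maternally expressed genes of other chromosomes have no such dosage, and their median change was at most -3.02 at either day. An indirect effect of a different number of chromosome 11 copies cannot be told apart from the lost Gcn5 or the line with 1 line per genotype, and the bound set beforehand (the lower imprinted genes elsewhere had a median of at most -3.49) was wrong for it, since it covers direct dosage alone. A delay in differentiation is argued against as the whole source. Null day 5 samples lay -4.02 (median, log2, middle quartiles -5.23 to -1.14) from floxed day 3 samples over the 8 maternally expressed genes. The bound of this test suits only genes that rise with time. Floxed values of Meg3 (-1.47), Rian (-1.03), Mirg (-1.26) and Phlda2 (-1.67) were lower at day 5 than at day 3. Null day 5 values of these lay below both floxed days, at -5.39, -4.80, -5.18 and -3.23 from floxed day 3. Grb10 (-5.67), Cdkn1c (-1.21) and Igf2r (-0.93) also lay below floxed day 3. For H19 alone (0.73 ± 0.47, within 2 SE of 0) a delay cannot be told apart. Whether a changed imprint at the H19/Igf2 and Meg3/Dlk1 regions is involved cannot be told apart. Only 2 of the 4 values of Igf2 (0.10 ± 0.29 and 0.57 ± 0.29) and Dlk1 (-0.17 ± 0.25 and -0.49 ± 0.25) were above 0. Each lay within 2 SE of 0, so their signs cannot decide it. Other imprinted regions were not part of this test. At day 5, 6 of the 16 paternally expressed genes rose and 1 fell. The risers included Airn (1.59, adjusted p = 0.0203, limma), on chromosome 17 like Igf2r, and Kcnq1ot1 (0.85, 0.0283), on chromosome 7 like Cdkn1c. Neither passed at day 3 (0.120 and 0.0945). Whether imprints changed there was not tested.

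Interferon response genes were higher in the null line at day 5. The direct dosage of chromosome 11 genes cannot be the whole source, since members on other chromosomes had a median change of 1.76. An indirect effect of a different number of chromosome 11 copies cannot be told apart from the lost Gcn5 or the line, and the bound set beforehand on these members (again 1.76) was wrong for it, since Irf1, a transcription factor gene on chromosome 11, rose by 1.31 and may act on genes elsewhere. The feeder fibroblast marker list gave no sign of added feeder RNA in null samples at day 5 (median -0.14, middle quartiles -0.31 to -0.03). The same list rose from day 3 to day 5 in the floxed line, so the embryoid bodies themselves may express these markers. It therefore cannot settle whether RNA from feeder fibroblasts adds to the rise at day 5. That source also stays open for the rise at day 3, when 4 of 14 markers rose and 0 fell. The interferon list's median was at least 1.71 under upper-quartile and TMM scaling. These moved the median change of all genes only from -0.02 to 0.02 and -0.003, so that test could hardly have come out otherwise. A scaling factor shifts nearly all genes of a library alike. The list's median of 1.70 against -0.02 over all genes argues against the scaling of the libraries as the source.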

How the results depend on the processing

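Chosen only after the data were seen were DESeq2, TMM scaling, leaving out the libraries numbered 3, and leaving out or centring chromosome 11 genes. So was the block joined with the compared groups alone or with a correction for GC content and length. EdgeR on the recovered reads was planned as an alternative, but its settings were not. The other alternatives were planned. Of 195 named gene and comparison pairs, every one kept direction and call under TMM scaling, no filter and both other pseudocounts. The number kept was 192 under upper-quartile scaling and with either edgeR setting, 193 with DESeq2 and with the replicate block, and 164 without the libraries numbered 3, where 28 calls were lost. Of these 10 were at day 3, namely Fgf5 (adjusted p = 0.109), Dusp6 (0.106), Spred3 (0.191), Cdk4 (0.0589), Pes1 (0.132), Ifih1 (0.118), Irf1 (0.0529), Tada2a (0.133), Taf9b (0.157) and Igf2r (0.125). At day 5 the 7 lost were Fgf5 (0.122), Spry4 (0.0805), T (0.104), Six6 (0.0504), Tdgf1 (0.108), Wnt3a (0.120) and Nodal (0.0524), and 11 were in the interaction. With only the groups compared 12 were lost: Meis2 (0.0978), Cplx2 (0.124), Ier3 (0.0560), Spred3 (0.0532), Ifih1 (0.109), Irf1 (0.0532), Taf9b (0.0619) and Igf2r (0.0949) at day 3, and Fgf5 (0.0656), T (0.0662), Tdgf1 (0.0566) and Nodal (0.0602) at day 5. Against a 1.5-fold change 102 were lost. Of 68 list calls, all kept direction and call under TMM and upper-quartile scaling, 66 with the block, 62 without the libraries numbered 3, 55 with a mean of at least 50, 47 with fry and 0 with an estimated correlation. Beyond Myc at day 3 and Kat2b in the interaction, the block changed no call among the named genes. It ended the primitive streak (adjusted p = 0.0518) and neural crest (0.0619) list calls in the floxed day comparison. For null against floxed samples it called more lists, 6 at day 3 and 17 at day 5, against 4 and 15 in the main test. Leaving out the libraries numbered 3 ended those of the primitive streak (0.0527) and Wnt (0.0757) lists at day 5, primitive streak (0.0641) and blood (0.112) between floxed days, primed epiblast (0.0505) between null days and cilia (0.0774) in the interaction. EdgeR gave 1013, 4588, 7138, 7468 and 71 genes (day 3, day 5, floxed days, null days, interaction), of which 982, 4412, 6995, 7394 and 71 were shared with limma in the same direction.

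Changed genes at day 3 (1041) numbered 1866 with the replicate block, 8 against a 1.5-fold change, 647 with only the groups compared, 3172 with these and the block, 2161 with the GC and length correction and block, 1694 with DESeq2, 382 without the libraries numbered 3, 388 without chromosome 11 genes, 456 with these centred, and 426 to 778 with 1 library left out. Those at day 5 (4509) numbered 203 against a 1.5-fold change, 2592 without the libraries numbered 3 and 3223 to 4073 with 1 library left out. Against a 1.5-fold change, 1830 changed between days in floxed, 1726 in null samples and 1 in the interaction. The interaction (81) gave 443 with the block, 509 with DESeq2, 35 without the libraries numbered 3 and 3 to 115 with 1 library left out. Fewer genes pass against 1.5-fold by construction. Leaving out libraries leaves fewer samples in a group and fewer residual degrees of freedom, which tends to lower the number of calls. A call lost this way does not by itself mark that library as deviating. How far the values of a library add to this was not tested, nor was the cause for the other alternatives.

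Lists called numbered 4, 15, 19, 15 and 15 in the order above, and 0 in each with an estimated correlation. Fry called 0 at day 3, 14 at day 5, 26 in the floxed day comparison, 23 in the null day comparison and 3 in the interaction. These were not all lists that camera called, and 21 camera calls were lost with fry. A mean of at least 50 left 2 at day 3. With 1 library left out, the numbers were 3 to 6, 13 to 16, 15 to 19, 13 to 16 and 12 to 20. The cause was not tested.

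Directions reversed for 6 values. With chromosome 11 genes centred, Pes1 (-0.00676) and Tada2a (-0.0539) turned at day 3, calls that were lost. The others were not called. At day 3, Igf2 was at -0.000267 without floxed day 3 replicate 1 and ranged from -0.122 to 0.229 over single libraries left out. Fgf8 ranged from -0.713 to 0.149. Dlk1 ranged from -0.478 to 0.0285 and was at 0.00809 without the libraries numbered 3. Kat2a in the floxed day comparison ranged from -0.0725 to 0.0349, was at 0.000296 and 0.0311 without floxed day 5 replicates 1 and 3, and was at 0.0797 without the libraries numbered 3. The cause was not tested. Depth limits the genes near 0 reads at day 3, and 1269 low genes were not tested.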

Other observations

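The tests of chromosome 11 in this part were written down before their results were seen; leaving out or centring its genes was chosen after.

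The lists that did not pass at day 5 (null against floxed) included the germ layers and other cell types an embryoid body may hold. In neural crest, 3 of 12 genes rose and 2 fell (adjusted p = 0.549; median -0.11, mean -0.07 and an upward test), and in definitive endoderm 3 of 12 rose and 4 fell (adjusted p = 0.549). In extraembryonic endoderm 2 of 25 rose and 3 fell (adjusted p = 0.928; median 0.03, mean -0.05 and a downward test). Cardiac mesoderm had 1 riser of 17 (adjusted p = 0.292), and epidermis and surface ectoderm 2 fallers of 8 (adjusted p = 0.302). Of mesenchymal genes 1 of 12 rose and 3 fell (adjusted p = 0.334), and of feeder fibroblast markers 1 of 14 rose and 1 fell (adjusted p = 0.661). No member passed in blood and endothelium (19 tested, adjusted p = 0.515), trophoblast (13, adjusted p = 0.875) or the Hox genes (18, median -1.21, adjusted p = 0.0942), by limma, adjusted over all genes or adjusted over the list alone.

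Among pathways, 3 of 21 Nodal and BMP genes fell and 1 rose (adjusted p = 0.0720), 6 of 15 ciliary genes fell and 2 rose (adjusted p = 0.210), and 5 of 24 p53 targets rose and 2 fell (adjusted p = 0.220). Of histone acetyltransferases and deacetylases 4 of 24 rose and 5 fell (adjusted p = 0.452), and of sex-chromosome genes 3 of 7 rose (adjusted p = 0.249). Adjusted over the list alone, the risers and fallers were 1 and 3 for Nodal and BMP, 2 and 6 for cilia, 6 and 2 for p53, 4 and 6 for the histone enzymes, 4 and 1 for sex-chromosome genes, 3 and 3 for neural crest and 3 and 5 for definitive endoderm; counts were the same as over all genes for the other lists of these paragraphs.

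Genes along the whole of chromosome 11 were higher in the null line at both days, which may come from a different number of copies of it in part or all of the cells of 1 line. In windows of 50 neighbouring genes, 100% of the 19 on chromosome 11 had a median log2 change above 0.15 at both days. Of the 209 windows on the other autosomes and the X chromosome, 0 did. No windows were made for the Y chromosome, which had 7 expressed genes. Their median was 0.20 at day 3 (71.4% above 0) and 0.33 at day 5 (100% above 0). Chromosome 11 was therefore not the only one with a higher median, and the cause for Y was not tested. Content of G and C and length are argued against, since matched genes of other chromosomes had a median of at most -0.0522. A single deviating library is argued against too. Each of the 6 null libraries had a chromosome 11 median of at least 0.31 (mean 0.37 ± 0.05 SD). Each library was set against floxed libraries of its day, so floxed values (-0.04 to 0.02) lie around 0 by construction. No p-value is given for this difference, since the values share that reference and the chromosome was picked from these data. An extra copy in every cell would give 0.58, so part of the cells or a partial response of expression stays open. Kat2a lies on chromosome 11, and with 1 line per genotype indirect effects of the copy number, the lost Gcn5 and the line cannot be separated for changed genes of other chromosomes.

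The 6 libraries of each comparison make 10 splits into 3 and 3, the real one included, too few for a share under 0.05. The real split was the 1 with the most genes in each: 1041 against at most 1 at day 3, and 4509 at day 5, 7094 in floxed and 7571 in null samples against at most 0. Other splits that part all same-numbered pairs gave at most 0. Every other split mixes the compared groups, so their difference enters its residual spread and few calls follow by design. These counts therefore say nothing on chance. For the interaction, 10 of 100 drawn splits of genotype within days gave at least 81 genes, up to 5174, a share that by itself does not exclude chance. All 9 of the other splits as large kept the day 5 libraries of a genotype together, so they carry the genotype difference as their structure and are no draws without a difference. The remaining 90 gave at most 1 gene, so these draws do not settle whether chance is excluded.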
